A study of Homo sapiens with 2 samples.

How the data were processed

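Total RNA of RKO cells was extracted with Trizol, and libraries were made with a Life Technologies protocol, per the labels' protocols. There were 2 libraries, 1 with a control siRNA and 1 with an siRNA against hnRNPU. The groups were taken from the treatment labels of the samples, and the sample titles name the siRNAs. The deposited table gave 1 FPKM value per gene and library (fragments per kilobase, scaled to library depth), computed by the authors before deposit. Bowtie and the genome build GRCh37 are named in the submitters' processing notes, without a version. The annotation, the counting program, the use of strand and the siRNA sequences are not given in the sources used here. FPKM corrects for depth and gene length as the authors defined them, and a few very abundant transcripts can shift the values of all others: the 10 highest genes held 23.3% of the FPKM sum in the control library and 22.5% in the knockdown library. Mitochondrial mRNAs and rRNAs took 12.0% and 11.5% of the reads.

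Read depth was read from the low values. In short noncoding genes whose span is their length, FPKM multiplied by length came in whole multiples of what 1 read adds, which gave 31801650 reads for the control library and 39807025 for the knockdown library. Within a tolerance of 1e-06 of a whole number, 65.3% and 63.8% of such genes held whole reads. Each FPKM value was then written as a ratio of whole numbers, which recovered reads and gene length in 16698 of the 17552 genes above 0 in both libraries (95.1%). In 2783 of these the ratio had the form left when reads are divided between similar or overlapping genes. A recovered read number can differ from the true number by a whole factor, since a common factor of reads and length is lost. In 2107 of 14638 genes with a GENCODE transcript the recovered length was under 0.5 of that transcript, and counting intervals are therefore approximate. Exact 95% Clopper-Pearson intervals of FPKM ratios were computed from these reads. They cover counting error only and say nothing of the variation between cultures. A gene of 2000 bases with 3 reads would have had 0.0472 FPKM in the control library and 0.0377 in the knockdown library.

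Ratios are log2 of (FPKM + 1) in the hnRNPU siRNA library over (FPKM + 1) in the control library. The pseudocount of 1 understates the difference of genes with low values. No further scaling was applied. A gene counted as at least 2-fold higher or lower at a log2 ratio of at least 1 or at most -1, with at least 5 FPKM in the higher library. With 1 library per group no test was possible and no p-value is given. Instead, 32 gene lists fixed before the data were examined were summarised by the median log2 ratio of their members with a mean of at least 1 FPKM. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these 2 libraries and is not a p-value. A list stood apart when its median lay outside the central 95% of the random lists, with a percentile under 2.5 or as far from the top, and lists with fewer than 5 measured members got no percentile. Of 775 names in the lists, 771 were matched to the table by symbol or through the gene identifier of the current RefSeq symbol. Some genes belong to more than 1 list.

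The genes named were also fixed by rule: HNRNPU, the 12 highest and 12 lowest log2 ratios with at least 5 FPKM in the higher library, and the 2 highest and 2 lowest members of each list. Clone names, small RNAs, pseudogenes and sex-linked marker genes were left out of that rule, as were 28 genes whose symbols had been turned into dates in the table. Further genes picked after their values were seen are marked as such. Some genes that the rule names are not reported here. No other value columns were used. Transcript length, base content, coding sequences and 3' UTRs came from GENCODE 29 through gene symbols, taking the longest transcript for length and the transcript with the longest 3' UTR of at least 50 bases for sequence. No coordinates were taken from it, since it uses another genome build. All 7-base words in the 3' UTRs of 8347 mRNAs with a mean of at least 3 FPKM were compared after trends with 3' UTR length, base content and expression had been removed, against 100 shuffles of the ratios. For GATGAC, the scan was repeated with 6-base words on each of 2 random sets of 4173 and 4174 of these mRNAs, and the lowest word of each was ranked in the other.

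Alternatives were pseudocounts of 0.1, 0.5 and 5 FPKM, rescaling to the same FPKM sum, by the median ratio or by the upper quartile, other minimum levels, and random lists not matched on expression. The 3 rescalings moved every gene by 0.03, -0.04 and -0.02 on the log2 scale. The steps were tested on simulated libraries drawn by Poisson sampling from the mean rate of 19193 genes at the real depths, with 200 genes changed by a known fold. Both depths were recovered exactly, as was the ratio of reads to length in 100% of 3000 genes. Only genes whose reads had already been recovered were simulated, with whole reads and lengths, so exact recovery was largely built in. It does not cover divided reads or genes whose reads were not recovered. Of the genes changed 3-fold or 4-fold, 100% passed the rule in the right direction. Of those changed 2-fold 14% passed, and of those changed 1.5-fold 0% (50 genes for each fold). Of 7301 unchanged genes, 6 passed the rule. The simulation held no variation between cultures, so more unchanged genes can pass it in real libraries. Counting intervals covered the true ratio in 95% of 2000 genes. Of 200 random lists, 6% fell outside the limits, and random lists of 25 real ratios moved by 0.1, 0.2 and 0.3 were recognised in 28%, 84% and 100% of 50 draws. Each of 5 words planted with a shift of -0.1 came out lowest in the scan. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.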

Results

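RNA was sequenced from RKO cells, an established human colorectal carcinoma line, after transfection with a control siRNA or with an siRNA against hnRNPU. Heterogeneous nuclear ribonucleoprotein U is a nuclear RNA- and DNA-binding protein, also known as scaffold attachment factor A. The question was how the mRNA profile of these cells differed once hnRNPU was knocked down. Each group held 1 library, so no difference below has a replicate check, no test across conditions was made, and "higher" and "lower" describe these 2 libraries only. The steps between low FPKM values gave 31801650 reads behind the control library and 39807025 behind the knockdown library, a ratio of 1.25. The file listed 40205 genes, and 11607 of them reached 1 FPKM in the control library and 11462 in the knockdown library.

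HNRNPU itself stood at 75.4 FPKM in the knockdown library and 239 FPKM in the control library, 31.5% of the control level. This is a log2 ratio of (FPKM + 1) of -1.65, and the FPKM ratio had an exact 95% counting interval of 0.310 to 0.320. The gene spans chromosome 1, positions 245013602 to 245027827 of GRCh37, on the minus strand. The 2 paralogues HNRNPUL1 and HNRNPUL2, which encode related RNA-binding proteins, had log2 ratios of -0.05 and 0.16. Next to HNRNPU, the noncoding HNRNPU-AS1 was listed at 0.508 FPKM against 2.52, a log2 ratio of -1.22 resting on 102 and 404 reads. Its listed span is positions 245003940 to 245010243 on the minus strand, the same strand as HNRNPU. COX20, an assembly factor of cytochrome c oxidase at positions 244998639 to 245006586 on the plus strand, was higher in the knockdown library, at 75.5 FPKM against 38.0 and a log2 ratio of 0.97. The spans of COX20 and HNRNPU-AS1 overlap, and whether the counting used strand is not given in the sources used here, so reads of these neighbours may be mixed. The paralogues and both neighbours were picked after their values were seen.

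**Figure D1:**
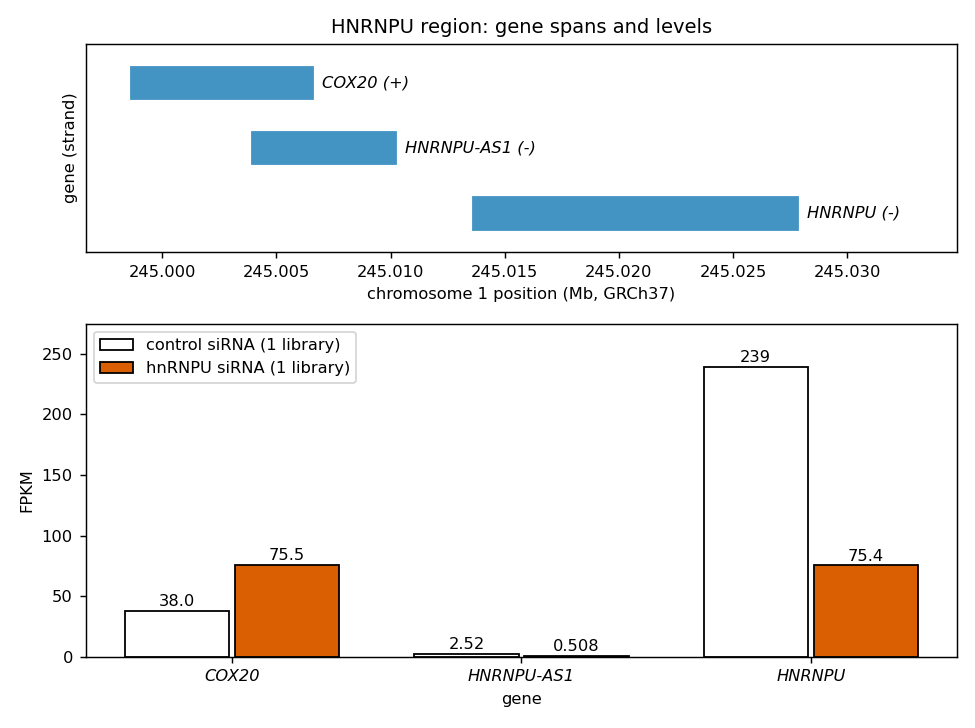
Gene spans on chromosome 1 (upper panel, position in Mb on GRCh37, strand in parentheses) and FPKM in the control siRNA and hnRNPU siRNA libraries (lower panel, bars, 1 library each). HNRNPU stood at 75.4 against 239 FPKM, HNRNPU-AS1 at 0.508 against 2.52 and COX20 at 75.5 against 38.0.

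ASNS, asparagine synthetase, had the lowest log2 ratio in the knockdown library at -2.03 (46.5 against 193 FPKM). PHGDH, which starts serine synthesis from a glycolytic intermediate, stood at -1.44 (31.1 against 85.8 FPKM). The membrane protein gene EMP1 (-1.78), the stress-response gene GADD45B (-1.59) and the hexosamine pathway enzyme gene GFPT2 (-1.44) were also among the 12 lowest. SRPR, the signal recognition particle receptor, had a log2 ratio of -1.57, and LMAN2, a cargo lectin of the secretory pathway, one of -1.44. CALD1, which encodes the actin-binding protein caldesmon, stood at -1.51, the nuclear envelope gene SUN3 at -1.44, the metallothionein MT1E at -1.42 and the tRNA-splicing endonuclease subunit TSEN15 at -1.39. HNRNPU ranked among them, between EMP1 and GADD45B.

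TOMM22, the central receptor of the mitochondrial outer membrane translocase, had the highest log2 ratio in the knockdown library at 1.48 (60.9 against 21.1 FPKM). EIF4A2, an RNA helicase of translation initiation, stood at 303 against 128 FPKM (1.24; counting interval of the FPKM ratio 2.33 to 2.41), and NOLC1, a nucleolar phosphoprotein, at 110 against 48.0 FPKM (1.18). DHX37, a helicase of ribosome assembly, had a log2 ratio of 1.08, as did YRDC, which acts in threonylcarbamoyl modification of tRNA. DPH5, an enzyme of diphthamide synthesis on elongation factor 2, stood at 1.09, and AHSA1, the activator of the HSP90 ATPase, at 1.04. The remaining members of the 12 highest were the transcriptional co-regulator IFRD1 (1.30), the zinc finger gene ZNF616 (1.20), MRFAP1 (1.18), the tropomyosin TPM4 (1.08) and the opioid growth factor receptor OGFR (1.07).

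**Figure D2:**
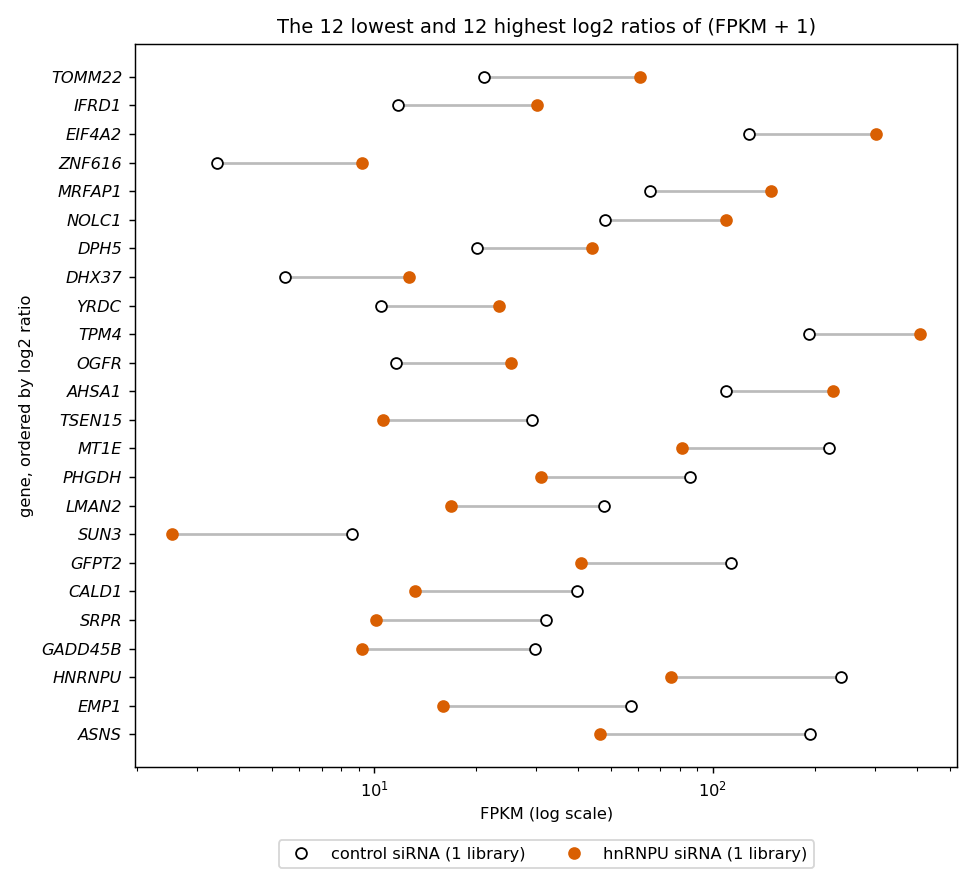
FPKM on a log axis for the 12 genes with the lowest and the 12 with the highest log2 ratio of (FPKM + 1) among genes with at least 5 FPKM in the higher library. Open circles are the control siRNA library and filled circles the hnRNPU siRNA library (1 each), and the genes run from ASNS at -2.03 to TOMM22 at 1.48.

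Among 7958 genes with at least 5 FPKM in the higher library, 25 were at least 2-fold higher in the knockdown library and 60 at least 2-fold lower. Restricted to mRNAs, the numbers were 15 and 46. At a log2 ratio of 0.5 the counts were nearly even, 488 higher and 493 lower, so the excess of lower genes held at the 2-fold rule. The bulk of the transcriptome differed little: 7277 genes with at least 5 FPKM in both libraries had a median log2 FPKM ratio of 0.04 with an SD of 0.34 across genes, and 59.0% of them lay within 0.25 of that median. The 6-base word GATGAC occurred in the annotated 3' UTR of 4 of the 12 lowest genes (HNRNPU, SRPR, CALD1 and LMAN2) and of 2 of the 12 highest (NOLC1 and MRFAP1). Of the genes with an annotated 3' UTR, it occurred in 20 of the 46 at least 2-fold lower and in 2 of the 15 at least 2-fold higher, against 2161 of all 7347. The word was taken from a scan of these same ratios, so its excess among lower genes was favoured by that choice and is no separate support. The 4 and the 20 include HNRNPU, the target of the siRNA. For DPH5, YRDC, LMAN2 and MT1E among these genes, the recovered reads had the fractional form left when reads are divided between genes. These 4 values are therefore less certain. The same limit holds for other genes named in the text, among them COX20, ATF4, RAD21, HSPA8, HSPD1, NCL, MALAT1, SRSF4, SRSF11, TCP1, CCT6A, EIF4H and EIF6. The count of higher genes depended on the minimum level, with 51 at 1 FPKM and 13 at 20 FPKM.

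Targets of ATF4 and of the unfolded protein response were lower as a list. Their median log2 ratio was -0.53, below all 10000 random lists of the same size and expression, and 18 of 25 measured members had a ratio below 0, 14 of them at -0.5 or less. ASNS and PHGDH were the lowest members. Others, singled out after their values were seen, were the glutathione-degrading CHAC1 (-1.33), the serine synthesis enzyme PSAT1 (-1.29), the cystine transporter SLC7A11 (-1.22), the transcription factor XBP1 (-0.81) and ATF4 itself (-1.06, at 132 against 276 FPKM). The list did not move as a block: DDIT3, which encodes the stress-induced factor CHOP, was higher at 51.4 against 28.3 FPKM (0.84), and the endoplasmic reticulum chaperone HSPA5 stood at 340 against 332 FPKM (0.03). SDF2L1 was the second highest member, with a log2 ratio of 0.31. The counting interval of its FPKM ratio, 0.69 to 2.37 on 30 and 19 recovered reads, included 1. HSPA5 was also singled out after its value was seen. GATGAC was present in the 3' UTR of 7 of the 25 members.

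Genes of mitosis were lower in the knockdown library by small amounts. In the list of G2 and mitosis genes, 27 of 30 members had a ratio below 0, with a median of -0.26 below all random lists, and 5 lay at -0.5 or less. CDC25C, the phosphatase that activates CDK1, had the lowest ratio (-0.77), followed by TOP2A, the topoisomerase of chromosome segregation (-0.73). The centromeric histone gene CENPA (0.23) and the checkpoint kinase gene BUB1B (0.01) were the highest. Chromosome architecture genes, of which TOP2A is also a member, had a median of -0.20 (percentile 0.03; 18 of 25 below 0), and 12 of the 25 carried GATGAC in the 3' UTR, against 3 of 30 in the G2 and mitosis list. LBR, the lamin B receptor, was lowest there at -0.97 (12.5 against 25.5 FPKM), the cohesin subunit RAD21, named after its value was seen, stood at -0.46, and the cohesin subunit STAG1 (0.48) and the lamin LMNB2 (0.30) were highest. S phase and replication genes did not stand apart, with a median of 0.08 (percentile 65.3), nor did replication-dependent histones at -0.01 (percentile 53.9) or double-strand break repair genes at 0.06 (percentile 75). The extremes of these 3 lists were CCNE2 (-0.30) and ORC1 (0.46), HIST2H2AC (-0.55) and HIST1H2AC (0.66), and MRE11A (-0.45) and RAD50 (0.48).

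MYC targets and ribosome biogenesis genes and heat shock protein genes were higher as lists. In the list of MYC targets and ribosome biogenesis genes, 27 of 30 members had a ratio above 0, with a median of 0.34 above all random lists. NOLC1 (1.18) and the U3 small nucleolar ribonucleoprotein subunit RRP9 (0.86) led this list. The abundant nucleolar protein genes NCL (918 against 1619 FPKM, -0.82) and NPM1 (-0.21) went the other way, and MYC itself stood at 0.17. Heat shock protein genes had the highest median of the lists, 0.55, above all random lists, with 13 of 14 members above 0. The constitutive chaperone HSPA8 stood at 1109 against 558 FPKM (0.99) and the mitochondrial chaperonin HSPD1 at 556 against 297 (0.90), with HSPA4L (-0.04) and BAG3 (0.05) lowest. Proteasome genes had a median of 0.20 with 24 of 27 above 0, led by PSMD11 (0.66) and PSMD12 (0.58), at a percentile of 97.2 that stayed just inside the central 95% of random lists. Cytosolic ribosomal protein genes were slightly lower, with a median of -0.10 (percentile 0.33; 39 of 51 below 0), led by RPLP1 (926 against 1876 FPKM, -1.02) and RPL12 (-0.72), while RPS14 stood at 0.25. Against random lists not matched on expression, the ribosomal proteins' percentile was 2.52, just inside the central 95%.

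The hnRNP family, without HNRNPU, did not stand apart, with a median of 0.04 over 28 members (percentile 47.0). Within it HNRNPD, an AU-rich element binding protein, stood at 255 against 450 FPKM (-0.82). HNRNPAB had the highest ratio of that list, 0.28. SR splicing factors had a median of -0.09 (percentile 2.54, just inside the limit), from SRSF11 (-0.57) to SRSF4 (0.61). Core spliceosome genes had a median of 0.13 (percentile 82.6), with the SF3B component PHF5A at 0.95 and SNRPA, the U1 protein A gene, at -0.33. Cajal body and snRNP assembly genes had a median of 0.14 (percentile 91.1) with 13 of 15 above 0, among them GEMIN5 at 0.61. The list labelled nuclear long noncoding RNAs was lower, with a median of -0.20 (percentile 0.38; 10 of 15 below 0). It was defined as abundant nuclear or cancer-associated long noncoding RNAs, so its median does not describe nuclear RNAs alone. MALAT1, a nuclear speckle RNA, stood at 248 against 433 FPKM (-0.80), CCAT1 at -0.69, TUG1 at -0.59 and the paraspeckle RNA NEAT1 at -0.30, while DANCR was higher (0.79). TUG1 and NEAT1 were named after their values were seen. Of the mRNAs reported to be stabilised by hnRNPU, 3 had a mean of at least 1 FPKM: IER3 (-0.69), GADD45A (-0.15) and HEXIM1 (-0.03).

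WNT targets were lower in the knockdown library, with a median of -0.22 (percentile 1.68; 9 of 12 below 0), led by the cyclin gene CCND1 at 52.2 against 98.3 FPKM (-0.90) and the surface receptor CD44 (-0.44). Genes of NF-kB signalling and inflammation were higher at a median of 0.27 (percentile 99.2; 8 of 10 above 0), led by the mitochondrial superoxide dismutase SOD2 (0.62) and the adhesion molecule ICAM1 (0.61), with NFKB1 at -0.36. That call was lost among members with a mean of at least 5 FPKM, at a percentile of 89.0, and with no minimum level, where the median was 0. ERK feedback and immediate early genes lay at -0.12 (percentile 2.93; ETV5 -0.83, PHLDA1 0.45), mesenchymal and matrix genes at -0.19 (percentile 3.06; CTGF -0.65, MMP1 0.58) and interferon-stimulated genes at -0.16 (percentile 3.83; IFIH1 -0.78, BST2 0.47). Cholesterol and fatty acid synthesis genes lay at 0.18 (percentile 96.5; DHCR7 0.63, INSIG1 -0.44) and hypoxia and glycolysis genes at 0.15 (percentile 94.4; PGAM1 0.50, CA9 -0.66). The p53 target list had a median of -0.03 (percentile 28.0) although its member GDF15, a secreted stress cytokine, stood at 6.66 against 16.7 FPKM (-1.21). Apoptosis regulators had a median of 0.04 (percentile 61.0), with cytochrome c, CYCS, at 32.7 against 15.9 FPKM.

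Oxidative phosphorylation genes of the nucleus had a median of 0.00 (percentile 15.2) and mitochondrial-encoded mRNAs one of -0.08 (percentile 11.0). Housekeeping reference genes centred on -0.01 (percentile 27.1), from SDHA at -0.40 to the transferrin receptor TFRC at 0.73. Epithelial and colon genes, 7 of which were measured, had a median of -0.11 (percentile 21.6), with EPCAM at 13.7 against 13.8 FPKM. Fibroblast and muscle markers reached at most 0.029 FPKM and neural and hepatic markers at most 0.069 FPKM in either library. Of the blood and immune markers, CD68 alone had a mean of at least 1 FPKM, at 282 against 212 FPKM. Of 28 lists with at least 5 measured members, 9 had medians outside the central 95% of random lists. For 28 lists of genes drawn independently of each other, 1.4 would lie outside. The members of a real list may vary together between cultures, and some lists share members, so 9 against 1.4 does not measure an excess over chance. How many lists would lie outside between cultures given the same siRNA could not be tested with 1 library per group.

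**Figure D3:**
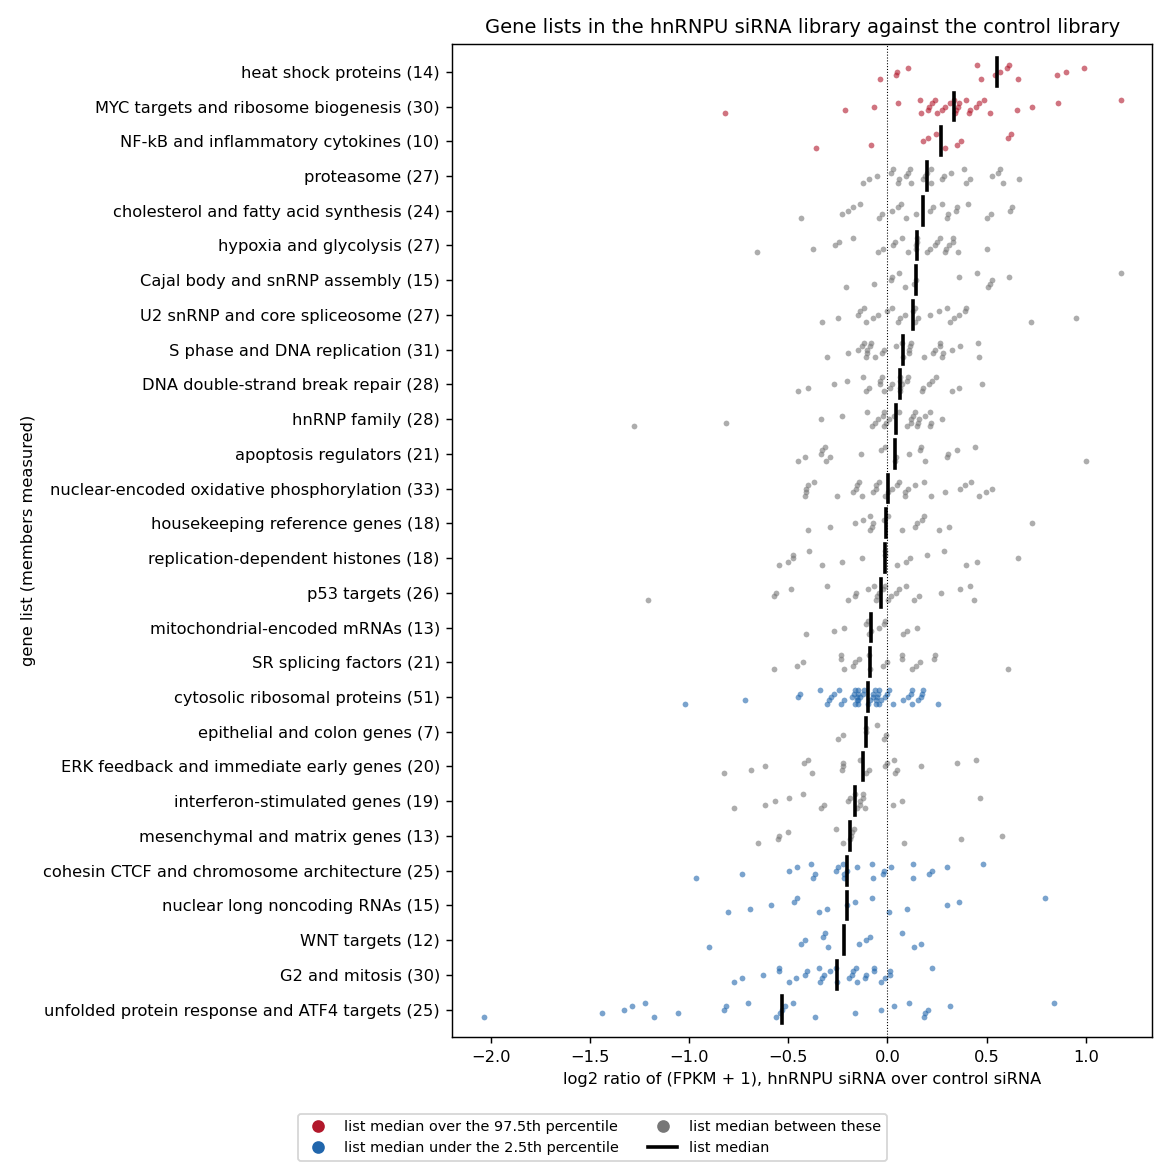
Log2 ratio of (FPKM + 1), hnRNPU siRNA over control siRNA, of each member (points) of the 28 lists with at least 5 measured members, with list medians as black bars and the number of members in parentheses. Heat shock proteins have the highest median (0.55) and targets of the unfolded protein response and ATF4 the lowest (-0.53), and colour marks the lists whose median lies outside the central 95% of random lists.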

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

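Restriction to mRNAs, to genes with an annotated 3' UTR or to those without GATGAC in it was chosen after the data were seen, as were the alternatives for the gene families and for GATGAC; the others were planned. No paired analysis was possible because each group had 1 library. The value of the HNRNPU knockdown lay outside its counting interval at a pseudocount of 5 FPKM (-1.61), after rescaling to the same FPKM sum (-1.62) and by the median ratio (-1.69), which follow from the added constant or factor itself. The count of genes at least 2-fold higher in the knockdown library, 25, was 9 at a pseudocount of 5 FPKM, 51 with no minimum or a minimum of 1 FPKM, 13 at 20 FPKM, 15 among mRNAs or among genes with an annotated 3' UTR, and 13 among those without GATGAC. The count of genes at least 2-fold lower in the knockdown library, 60, was 24 at a pseudocount of 5 FPKM, 30 at 20 FPKM and 26 among genes with an annotated 3' UTR and no GATGAC. A larger pseudocount shrinks all ratios, the restrictions and higher minimums leave fewer genes, and lower minimums admit more. Of 277 comparisons of list medians with an alternative, 254 kept their side of the limits, 20 moved a list past a limit it had missed and 3 brought a list back inside. Those 3 were the ribosomal proteins against unmatched random lists (median -0.10), and the NF-kB list with no minimum level (median 0) and at 5 FPKM (median 0.25); the cause was not tested. The median of the chromosome architecture list, with GATGAC in 12 of 25 members, was -0.22 (percentile 0.07) over the members without it. Lists such as SR factors, ERK feedback, mesenchymal, interferon, cholesterol and proteasome genes lay near a limit and passed it under 1 or more alternatives. Depth limited the precision of low genes: the FPKM ratio of HNRNPU-AS1, on 102 and 404 reads, had a counting interval of 0.161 to 0.251, against 0.310 to 0.320 for HNRNPU.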

Other observations

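The families below were grouped by symbol, and the 3' UTR words were scanned, after the values had been seen. Also chosen after the result was seen were the tests of base composition, of microRNA-like silencing and of GATGAC sites in the list of unfolded protein response and ATF4 targets, and those of differences between the dishes. All 5 measured metallothioneins, which bind zinc and copper, were lower in the knockdown library, with a median log2 ratio of -0.81 (percentile 0.01); MT2A stood at 943 against 2062 FPKM and MT1X at 114 against 200. The reads of MT2A and MT1E had the divided form, so their split between near-identical copies is uncertain. Cytosolic aminoacyl-tRNA synthetases, many of which ATF4 is known to induce, had a median of -0.26 below all random lists, with 13 of 17 below 0, led by CARS (-1.05) and WARS (54.4 against 110 FPKM), while KARS stood at 0.56. Kinesins had a median of -0.20 (percentile 0.06; 16 of 26 below 0), the mitotic KIF11 at -0.33 and the transport motor KIF1C at 0.83. All 8 subunits of the chaperonin TRiC, which folds actin and tubulin, were higher (median 0.39, percentile 99.9), TCP1 at 0.74 and CCT6A at 0.66. Mitochondrial ribosomal proteins (median 0.19, percentile 99.9; 63 of 76 above 0) and mitochondrial import genes (0.22, percentile 99; 18 of 23 above 0) were higher too, among the latter TOMM22 and TOMM40 (0.53). Of 354 zinc finger genes named ZNF, 254 had a ratio above 0 (median 0.15, above all random lists). Genes named EIF, translation initiation factors with their regulators and pseudogenes, had a median of 0.16 (percentile 99.8) over wide differences, from EIF4H at -1.10 to EIF6 at 0.83 and EIF4A2 at 1.24. Nucleolar genes named UTP or NOP (0.23, percentile 98.6) and subunits of RNA polymerases I and III (0.24, percentile 98.0) were higher as well. Both share members, such as NOP56, UTP20 and POLR1A, with the list of MYC targets and ribosome biogenesis genes, so they are not independent of it. The kinesins likewise share members such as KIF11 with the G2 and mitosis list. Of 17 families with at least 5 members, 10 had medians outside the central 95% of random lists.

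The mRNAs whose 3' UTR held GATGAC were lower. GATGACA had the lowest z of 16384 words of 7 bases (-10.7, in 1134 mRNAs), followed by AGATGAC (-9.03) and TGATGAC (-8.97), against a lowest z of -4.85 in any shuffle. In the other direction 4 words passed every shuffle (highest z 4.79), TAATCCC (5.45), GGAGAAA (5.20), TGGAGAA (5.01) and GGAGAAT (4.86). Compared with 3732 mRNAs with GATGAC neither in the 3' UTR nor in the coding sequence, those with 1, 2 and at least 3 copies in the 3' UTR differed by -0.11, -0.15 and -0.19 on the adjusted log2 scale. A bare copy went with -0.066 ± 0.018 (SE across genes, which are not independent replicates). A copy with A after it and A or T before it went with -0.16 ± 0.012, although these flanking bases were taken from the scan itself. The first class excluded mRNAs with any such flanking base and the second needed only 1 such copy, so copy number was not held equal. In the scan, mRNAs with CGATGAC (179) differed by -0.11, those with AGATGAC by -0.090 and those with TGATGAC by -0.091. A or T before the word was thus not set apart from C, which the bare class can hold. HNRNPU carried 3 copies of GATGAC in its annotated 3' UTR and 0 in its coding sequence. The difference between mRNAs with and without the word lay between -0.070 and -0.11 under 8 other settings.

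Base composition of the 3' UTR is argued against as the whole cause: with the mRNAs divided at random into 2 sets, GATGAC was the word with the lowest z in each, and in the other set it ranked 1 of the 180 words made of its 6 bases, at -0.097 and -0.087 against -0.055 and -0.046 for the next. Over both sets together the next words were CGATGA (-0.051) and ATGACG (-0.040), which can overlap GATGAC and so are not unrelated to it. A candidate explanation is microRNA-like silencing through an siRNA strand whose seed pairs with GATGAC. The mRNAs with a copy in the 3' UTR differed by -0.038 ± 0.012 (SE across genes) from those with copies in the coding sequence alone. The former could also hold copies in the coding sequence, so this does not show that a 3' UTR copy weighs more. The SE of 0.012 joined the SEs of both groups against the same 3732 mRNAs. Their spread was thus counted 2 times, and the value overstates the SE between the 2 groups. Against the same 3732 mRNAs, copies in the coding sequence alone went with -0.086. Among the same 180 words in the coding sequence alone, the next reached -0.070 and the median of the others was -0.018. That next word, TGACGA, can overlap GATGAC as well. Within those 3732, mRNAs with the reverse complement in the 3' UTR differed by 0.012 ± 0.012 from those without it. The siRNA sequence is not given in the sources used here, and with 1 library per group a difference between the 2 dishes unrelated to the siRNA cannot be told apart from it.

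The list of unfolded protein response and ATF4 targets was lower at its median, although 7 of its 25 members, DDIT3 among them, had a ratio above 0. GATGAC sites in the members' own 3' UTRs are argued against as the whole cause. The 18 members without a site kept a median of -0.44, below all random lists, beside -0.56 for the 7 with a site. Copies in coding sequences, or in mRNAs that regulate these members, were not covered. A trend with transcript length or GC content over all genes was small, running from -0.13 at the 1st percentile of genes to 0.04 at the 99th and making up 1.27% of the variance, so it is argued against as the whole cause; the median stayed at -0.53 without it. A response to the loss of hnRNPU stays open, with no test of its own. With 1 library per group, it cannot be told apart from a difference between the dishes such as medium or density. Nor can it be told apart from silencing of other mRNAs by the siRNA.

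Heat shock, ribosome biogenesis and proteasome genes, pooled after their medians had been seen, had a median of 0.31 over 71 measured members, although the proteasome list alone did not stand apart (percentile 97.2). The same small trend with transcript length or GC content is argued against as the whole cause, since the median was 0.32 without it. Reads shared with near-identical copies are argued against too, because the 56 members whose reads had not been divided had a median of 0.30. A response to the loss of hnRNPU may underlie the pattern, as a hypothesis with no test of its own. A difference between the dishes, such as growth rate or temperature, cannot be told apart from it with 1 library per group. Nor can silencing of other mRNAs by the siRNA.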
